A study of Homo sapiens with 12 samples.

How the data were processed

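Total RNA from cells labelled HepG2, a line derived from a human hepatocellular carcinoma, was hybridized to one-colour oligonucleotide arrays after labelling with Cy5. Per the labels, 3 arrays came from mock-treated control cells and 3 each from cells given 25 µM glycyrrhizin, silymarin or ursodeoxycholic acid, so 12 arrays were read in 4 groups. Nothing in the labels says that the 3 arrays of a group came from separate cultures. The p-values therefore measure the spread between these arrays, which may be technical. Treatment time, scanner, background correction and any batch or slide are not given in the sources used here.

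The authors deposited 1 intensity per probe and array on a linear scale, with limma named in the submitters' processing notes and its steps not given in the sources used here. The values had been brought to 1 common distribution before deposit: at a given rank the values on the 12 arrays spread by a median of 1.22%, and 100% of the values under 9000 lay on steps of 1/24, within 0.02 of a step. The deposited intensities ran from 1 to 65221, with a median of 86.1 over all probes. Array medians lay between 85.8 and 86.6. No detection call accompanied the values used here, so a dim probe could not be told from background, and the number of arrays limits the precision.

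The table held 27561 probes. Of these, 15650 had 1 gene symbol in the platform annotation, 0 had several and 11911 had none, and the last were kept out of every comparison of genes. Symbols were set against a current table of human genes: 2100 older symbols were updated, 58 with several possible updates were kept as given. The remaining probes named 13881 genes. A gene was represented by its probe with the highest mean over the 12 arrays. For the 1674 genes with more than 1 probe, the brightest and dimmest probe lay a median of 1.68 log2 units apart, and 707 genes had a gap of at least 2.

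Intensities were log2-transformed and fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 mean per group over all 12 arrays, so that the groups shared one estimate of the spread (8 residual and 2.8 prior degrees of freedom). From that fit came 7 comparisons: each agent against control, the mean of the 3 agents against control, and the 3 pairs of agents. Tests were two-sided, and p-values were adjusted over the 13881 genes by the Benjamini-Hochberg method with a threshold of 0.05. By chance, a mean of 694.1 genes would lie under an unadjusted p of 0.05. Genes on the same arrays are correlated, and the spread of that count was not estimated. Intervals are 95% intervals from the same fit. Values per group are means with the SD over 3 arrays, and effects are log2 differences with the standard error (SE).

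Sets of genes were tested with camera (preset correlation 0.01) on 34 gene lists, covering pathways of liver metabolism, xenobiotic response, stress, growth, cell machinery and markers of other cell types. The adjustment was over the 34 lists of a comparison. The same lists were tested with an estimated correlation and with fry, which asks whether a list's genes move on balance in one direction without comparing them with other genes. A member's p was also adjusted over its list alone. That adjustment takes no account of the 34 lists, so in each comparison some lists may hold such a member by chance.

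Groups, tests, gene lists, most alternatives and the rule for naming genes were set before the data were examined. The rule named, for each agent, the genes with the largest change past the threshold, or the 5 with the smallest p in a direction where fewer than 3 passed, and the members of each list with the smallest p. For each pair of agents it named the genes with the largest differences past the threshold. Which of the list members so chosen the text names was decided after their values were seen. Genes named outside the rule are said to have been chosen after their values were seen.

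Alternatives covered the replicate number as a block, renormalization, leaving out dim probes, other ways of joining probes, a variance trend with robust estimation, array weights, fits on the compared groups alone, a 2-fold limit and leaving out each array in turn. Offsets of 16 and 50 added before the log, and the gene lists without each array, were added after seeing the data. Comparisons that share the control arrays were set against 100 simulations of unchanged groups. The test was checked on simulated arrays built from the means and spreads of the 13881 genes, with 200 genes changed in the comparison of glycyrrhizin with control. In 10 runs the main setting found 15.3% of the 2-fold changes and 64% of the 4-fold changes, with 4.12% of the calls false. With the variance trend these were 21.1%, 65.2% and 4.31%. The simulated noise was drawn independently for each probe and array, so the shares on the real arrays may differ.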

Results

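The series measured gene expression in cells labelled HepG2 and exposed to 3 hepatoprotective agents, to ask which genes each agent affects and whether the agents share a response. Glycyrrhizin is a triterpenoid saponin of liquorice root, silymarin a mixture of flavonolignans from milk thistle, and ursodeoxycholic acid a hydrophilic bile acid. Each was given at 25 µM. Each group comprised 3 arrays, and 13881 genes were measured on all 12. Arrays of the same group correlated across probes with a median r of 0.934, and arrays of different groups with a median r of 0.933, where probes are not independent replicates. The residual SD fell with brightness, from a median of 0.67 log2 units in the dimmest of 4 equal groups of genes to 0.24 in the brightest.

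Transcripts of secreted liver proteins were measured near the middle of the intensity range in all groups. The median gene lay at a log2 intensity of 6.7. The median was 6.43 over 27 coagulation and complement genes, 6.46 over 16 apolipoprotein and lipoprotein assembly genes, 6.75 over 16 acute phase proteins and 6.55 over 22 hepatocyte identity genes. Apolipoprotein APOA2 averaged 5.17 over the 12 arrays, transferrin TF 6.4, fetal serum protein AFP 6.89 and antitrypsin SERPINA1 6.8. Brighter were the apolipoproteins APOB at 8.89, APOA1 at 7.66 and APOE at 7.43 and transthyretin TTR at 7.77. By contrast, 26 proteasome subunits had a median of 10.31 and 31 genes of oxidative phosphorylation a median of 9.51. Of 9 leukocyte markers the median was 6.86, of 12 endothelial and cholangiocyte markers 6.77, and of 9 fibroblast and stellate cell markers 6.16. None of these 3 marker lists passed the camera test in any comparison of an agent with control, for which the lowest adjusted p over all 34 lists was 0.193.

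**Figure D1:**
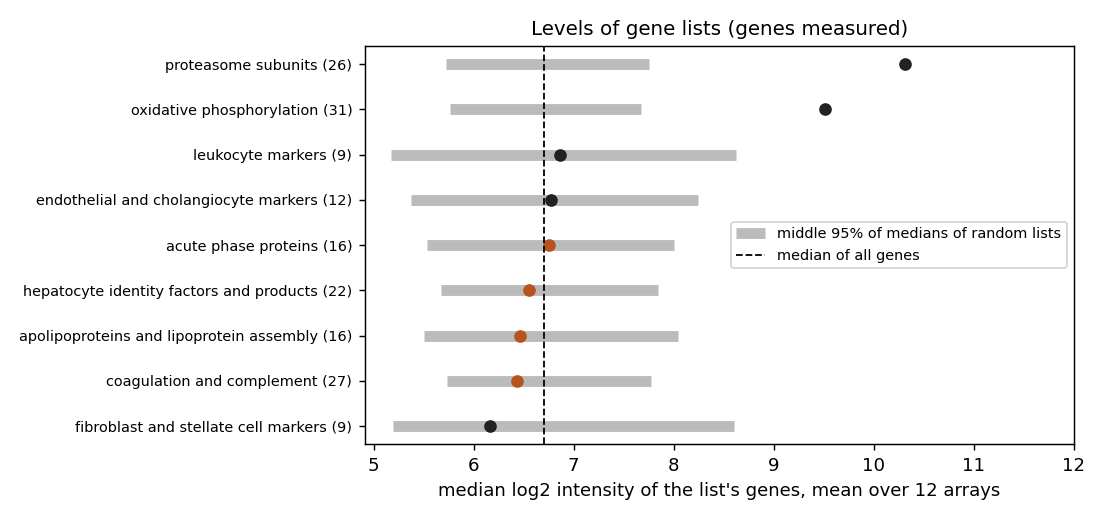
Median log2 intensity of the genes of 9 lists (points, mean over the 12 arrays, number of genes measured in parentheses) with the middle 95% of the medians of 10000 random gene lists of the same size (bars) and the median of all genes (dashed line). The 4 lists of liver products, in orange, lie between 6.43 and 6.75, inside their bars, while proteasome subunits (10.31) and oxidative phosphorylation (9.51) lie above theirs.

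Glycyrrhizin against control. The 5 genes with the lowest p-values were measured lower with glycyrrhizin, 3 of them bright. MIEN1, a membrane-anchored regulator of cell migration, averaged 12.03 ± 0.01 (SD, n = 3) in control and 10.48 ± 0.1 with glycyrrhizin, 2.92-fold lower on 3 of 3 arrays (log2 difference −1.54, SE 0.18). Its adjusted p from limma was 0.0512, so it did not pass. The chloride channel gene CLCN2 was 2.54-fold lower (adjusted p = 0.101) and CYP1A2, a xenobiotic-metabolizing cytochrome, 2.52-fold lower (adjusted p = 0.165). CYP1A2 has 1 probe, which averaged 10.68 over the 12 arrays, against a median of 6.55 over 22 hepatocyte identity genes. Whether so bright a probe reads the CYP1A2 transcript was not tested, and each result given for CYP1A2 rests on it. The bone morphogenetic protein antagonist CHRDL1 and DCAF10, a substrate receptor of a ubiquitin ligase, differed by −2.27 (SE 0.32) and −3.48 (SE 0.53) at low intensity. On the higher side, the 5 smallest p-values belonged to SYCE2, RHOJ, UBE2N, FNDC8 and SLC15A1, with log2 differences of 1.72, 1.76, 2.1, 1.32 and 1.4. All 5 averaged under the median gene, and none passed.

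Among genes of the aryl hydrocarbon receptor (AhR) list, 2 of 6 measured members passed when adjusted over the list alone, CYP1A2 (adjusted p = 0.000356) and CYP1B1 (log2 difference −0.72, adjusted p = 0.00919). Each of 4 other lists held 1 member that passed when adjusted over the list alone. These were FDFT1, the squalene synthase of cholesterol synthesis (−1.28), the proteasome subunit PSMB5 (−1.03), the metalloproteinase inhibitor TIMP3 (−1.52) and the liver-type phosphofructokinase PFKL, measured higher by 0.73. None of the 6 passed over all genes. Other members with low p-values were the cholesterol enzyme NSDHL (−0.4), the proteasome subunit PSMD14 (−1.05), hexokinase HK1 (0.45), malic enzyme ME1 (−0.54), superoxide dismutase SOD1 (0.48), the signalling inhibitor SMAD7 (−1.03) and the immediate early genes FOS (−1.04, or −0.45 without glycyrrhizin replicate 1) and KLF4 (−0.64), none past either adjustment. The bile acid conjugating enzyme BAAT differed by 0.98 (SE 0.29), the oxysterol hydroxylase CYP7B1 by −0.97 (SE 0.33), AFP by −0.73 (SE 0.21) and TF by −0.74 (SE 0.28), again without passing.

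With limma and Benjamini-Hochberg adjustment, 0 of 13881 genes changed, while 746 lay at an unadjusted p under 0.05 against 694.1 by chance. The variance trend setting called 17 genes, 1 higher (PFKL) and 16 lower, including MIEN1, CLCN2, CYP1A2, PSMB5, the kinase gene HIPK3 (−1.56), the mitochondrial regulator MTERF3 (−1.28), the nuclear envelope protein SYNE2 (−1.46) and OAF (−0.94), the last 4 chosen after their values were seen. Camera, camera with an estimated correlation and fry each called 0 of 34 lists, with 1 at an unadjusted camera p under 0.05, and the lowest adjusted p was 0.577, for the AhR list. Camera called that list lower when the dimmer 50% of probes were left out, which kept 3 of its genes. That cut dropped ALDH3A1, at 5.95 to 6.45 with glycyrrhizin and 5.48 to 6 in control.

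Silymarin against control. The smallest p belonged to DCPS, the scavenger enzyme that hydrolyses the cap left by mRNA decay. It averaged 11.25 ± 0.45 (SD, n = 3) in control and 8.41 ± 0.67 with silymarin, 7.15-fold lower (log2 difference −2.84, SE 0.33, adjusted p = 0.0587 in limma), which did not pass. The cartilage collagen COL2A1 was 2.39-fold lower (−1.26, SE 0.2, adjusted p = 0.24). CHRDL1 (−1.9), the nuclear cap-binding subunit NCBP1 (−2.42) and the kinase MAP4K5 (−1.91) were dim and did not pass. On the higher side stood SYCE2 (2.19), the matrix protein tenascin C (TNC, 1.68), CDH22 (2.1), RHOJ (1.74) and PIP4P1 (1.16), of which PIP4P1 alone was above the median gene, and again none passed.

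CYP1B1, a cytochrome of the AhR list, averaged 8.83 ± 0.2 in control and 9.77 ± 0.13 with silymarin, and was the 1 listed member that passed when adjusted over the list alone (log2 difference 0.93, adjusted p = 0.00295). Over all genes its adjusted p was 0.525, and 1 such member among 34 lists could arise by chance. The receptor gene AHR itself differed by 0.37 (SE 0.2). Of 20 measured interferon-stimulated genes 16 lay above control, among them IFIT1 (0.77) and OASL (0.48), and the list's adjusted p was 0.199. Of 20 genes of G2 and mitosis 13 lay below control (adjusted p = 0.199), with cyclin CCNA2 at −0.64 and the spindle factor TPX2 at 0.72. Lysosomal CTSB (−1, or −0.55 without silymarin replicate 1) and GLA (0.44), the glucocorticoid-responsive DUSP1 (0.91) and HSD11B1 (0.87, or 1.34 without silymarin replicate 1), the stress response genes ASNS (0.82) and DDIT3 (0.81, or 0.52 without control replicate 2), and FDFT1 (−1.07), SQLE (0.43), BAAT (0.65) and the transporter SLCO1B1 (−1.06) were the other members with low p-values, none past the threshold.

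Limma called 0 genes with silymarin, with 679 at an unadjusted p under 0.05, fewer than the 694.1 given by chance. The variance trend called 4, all lower: DCPS, COL2A1, CCNA2 and the lysyl oxidase relative LOXL1 (−0.95), the last chosen after its values were seen. Camera, its estimated-correlation form and fry called 0 lists, with 5 at an unadjusted camera p under 0.05. When probes in the dimmer 50% were left out, camera called the G2 and mitosis list lower over 13 genes and the AhR list higher over 3 genes. CYP1A2, 1 of those 3, lay at 11.1 to 11.42 with silymarin and at 11.2 to 11.39 in control.

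Ursodeoxycholic acid against control. As with glycyrrhizin, MIEN1 and CLCN2 were among the 5 genes with the smallest p on the lower side. MIEN1 averaged 10.73 ± 0.2 (SD, n = 3), 2.45-fold below control, and CLCN2 averaged 10.1 ± 0.19 against 11.39 ± 0.03, 2.44-fold below it. Both had an adjusted p of 0.0738 in limma and did not pass. The same adjusted p applied to the dim genes KLHL40 (−2.44) and SLC22A11 (−2.64), an organic anion transporter. SYNE2 was 3-fold lower (log2 difference −1.58, SE 0.25, adjusted p = 0.155). The 5 genes with the smallest p on the higher side were SYCE2 (1.88), TNC (1.77), the mitochondrial ribosomal protein MRPL47 (1.8), UBE2N (2.15) and AMMECR1L (1.04), which were dim and did not pass.

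CYP1A2 was 2.21-fold lower, and with the aldehyde dehydrogenase ALDH3A1, higher by 0.92, passed when adjusted over the AhR list alone (adjusted p = 0.0013 and 0.0213). FDFT1 differed by −1.35 and passed over the cholesterol list alone (adjusted p = 0.0101), and its listed neighbour SC5D differed by −2.07 with an SE of 0.78. None of these passed over all genes. Of 11 measured cytosolic ribosomal proteins 10 lay below control, RPS16 at −0.63 and RPL37 at −0.37, although RPL37 turned to 0.09 when its probes were averaged. The list's adjusted p was 0.193. The same value applied to 19 G1 regulators and immediate early genes, of which 14 lay below control (FOSB −1.26, FOSL1 −1.06), and to 15 drug metabolism enzymes, of which 11 did (CYP3A5 −1.07, CYP2C8 −0.87). The bile acid uptake transporter SLC10A1 (0.74), CYP7B1 (−0.77), the proliferation genes MKI67 (−1.44) and TTK (−1.08), and the coagulation factors F12 (−1.25) and F10 (−1.76) did not pass. Several of these values rested on ursodeoxycholic acid replicate 1, the array with the lowest median correlation with the other 11 (r = 0.923) and the lowest array weight (0.55). Without it CYP3A5 differed by −0.48, CYP2C8 by −0.29, FOSL1 by −0.55, F10 by −1.1, RPS16 by −0.28 and RPL37 by −0.19, while without replicate 2 FOSB differed by −0.82 and RPS16 by −1.24, and without replicate 3 MKI67 differed by −2.19 and RPS16 by −0.38. RPL37 differed by −0.62 and −0.18 without control replicates 2 and 3.

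Limma called 0 genes with ursodeoxycholic acid, with 734 at an unadjusted p under 0.05. The variance trend called 6, all lower: MIEN1, CLCN2, SYNE2, CYP1A2, OAF (−1) and the replication factor GINS4 (−2.44), the last 2 chosen after their values were seen. Camera called 0 lists, as did the estimated correlation and fry, with 4 at an unadjusted camera p under 0.05. Without ursodeoxycholic acid replicate 3, limma called KLHL40 (−2.73) and FREM1 (−2.08), both lower, the second chosen after its values were seen. On all arrays FREM1 differed by −1.26, with 2 of 3 arrays below control and replicate 3, at 8.7, above it, and by −0.77 without replicate 1. Without ursodeoxycholic acid replicate 2 camera called the ribosomal list lower (adjusted p = 0.0251, against 0.18 to 0.838 without any other array).

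The 3 agents together. A shared response was sought as genes changed by all 3 agents in the same direction and as the mean of the 3 agents against control. The lowest p-values of the mean belonged to CHRDL1, with a log2 difference of −2 (SE 0.26), and SYCE2, a synaptonemal complex gene higher by 1.93 (SE 0.25), both with an adjusted p of 0.0849 and both dim. Each lay beyond all control arrays on 9 of 9 treated arrays, which adds little for genes picked by their low p in this comparison. MIEN1 (−0.93) and SYNE2 (−1.28) followed at an adjusted p of 0.243, with CLCN2 at −0.85. These 5 were chosen after their values were seen. No gene passed with all 3 agents in limma or with the variance trend. The limma count was fixed at 0 by the 0 calls for each agent, and the variance trend called few genes per agent. These counts therefore do not show that a shared response is absent. At an unadjusted p under 0.05 in each comparison 45 genes were higher and 29 lower. Those 74 genes compare with a mean of 78 in simulations of unchanged groups that share 1 control group. The middle 95% of the simulations ran from 0 to 362.7, too wide for the closeness of 74 to 78 to decide anything. Independent lists would give 0.24 and 0.23.

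For the mean of the agents limma called 0 genes, with 591 at an unadjusted p under 0.05, and the variance trend called MIEN1, SYNE2 and CLCN2. For MIEN1 and CLCN2 the mean rested on 2 agents, since silymarin differed from control by 0.05 (95% interval −0.35 to 0.45) and 0.07 (−0.33 to 0.47) and 6 of 9 treated arrays lay below the control arrays, against 9 of 9 for SYNE2 (−0.79 with silymarin). Camera called 0 of 34 lists (lowest adjusted p = 0.478, 1 at an unadjusted p under 0.05), as did the estimated correlation and fry. Across genes, which are not independent replicates, the log2 differences of glycyrrhizin and ursodeoxycholic acid correlated at r = 0.47. Those of glycyrrhizin and silymarin correlated at 0.41 and those of silymarin and ursodeoxycholic acid at 0.38. The mean r of simulated unchanged groups was 0.48 in each case. The middle 95% of the simulated r ran from −0.21 to 0.8, from −0.21 to 0.76 and from −0.19 to 0.84 in that order, so all 3 values lay inside. The covariances were 0.101, 0.083 and 0.083 against simulated means of 0.119, 0.117 and 0.115. They too lay inside the middle 95%, from −0.014 to 0.281, from −0.008 to 0.238 and from −0.017 to 0.243. The variance trend calls of glycyrrhizin and ursodeoxycholic acid had 5 genes in common, MIEN1, CLCN2, CYP1A2, SYNE2 and OAF, where independent lists would share 0.0073, a figure that takes no account of the shared control arrays. Neither list shared a gene with the 4 called for silymarin.

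Glycyrrhizin against silymarin. This pair had the most genes past the threshold in limma, 7, 2 higher with glycyrrhizin and 5 lower. DCPS was 8.17-fold higher with glycyrrhizin (log2 difference 3.03, SE 0.33, adjusted p = 0.0153), averaging 11.44 ± 0.22 with glycyrrhizin and 8.41 ± 0.67 with silymarin, with control at 11.25 and ursodeoxycholic acid at 11.38. NCBP1 was higher by 3.04 (SE 0.41, adjusted p = 0.0329), though its mean log2 intensity of 3.85 ranked in the lowest 1.5% of genes and its silymarin arrays, at 0.87 to 2.35, lay near the lowest deposited value, so that no fold is given. CYP1B1 was 3.15-fold lower with glycyrrhizin, at 8.11 ± 0.1 against 9.77 ± 0.13 (SD, n = 3), with control between them at 8.83 (adjusted p = 0.0153). HIPK3 was 3.9-fold lower, MTERF3 3.23-fold, MIEN1 3.02-fold and CLCN2 2.66-fold, with adjusted p-values of 0.0313, 0.0329, 0.0153 and 0.0313. Each of the 7 lay beyond all silymarin arrays on 3 of 3 glycyrrhizin arrays, as chance gives for 10% of genes.

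**Figure D2:**
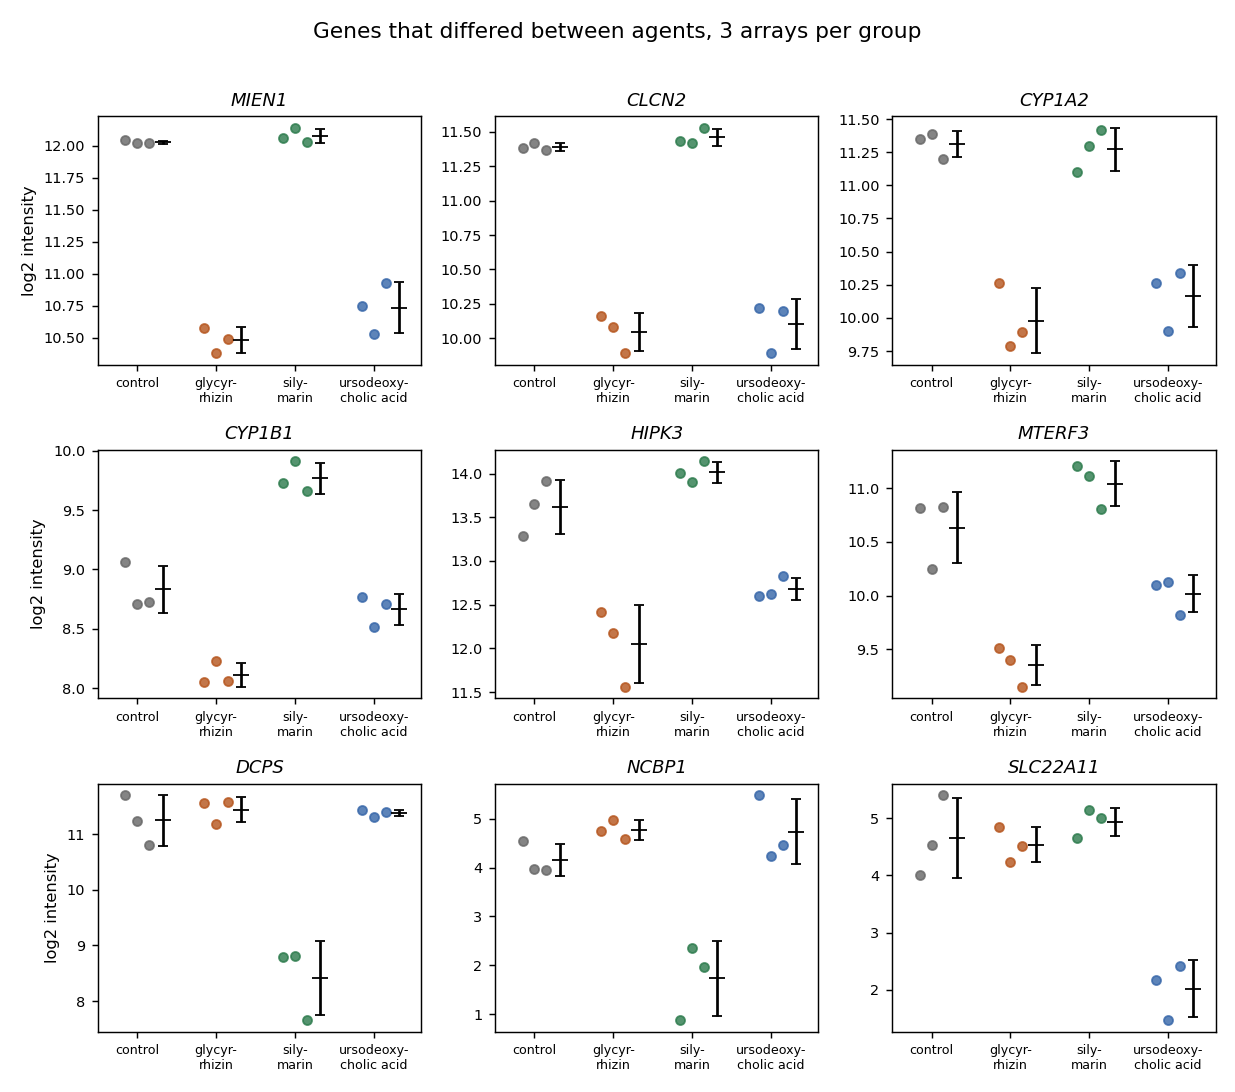
Log2 intensity on each array (points) with the group mean and SD (bars, n = 3) for the 8 genes that passed between agents and for CYP1A2. MIEN1 and CLCN2 lie near 12.03 and 11.39 in control and at similar levels with silymarin, and near 10.48 and 10.05 with glycyrrhizin, with ursodeoxycholic acid close to glycyrrhizin; DCPS is low with silymarin.

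The AhR list was lower with glycyrrhizin than with silymarin (5 of 6 measured members lower, camera adjusted p = 0.0336; fry 0.00202), and its members CYP1B1 and CYP1A2 (−1.29) both passed when adjusted over the list alone. With an estimated correlation the list's adjusted p = 0.33. When the dimmer 50% of probes were left out, camera called 4 lists lower with glycyrrhizin. These were the AhR list over 3 genes (adjusted p = 0.000946), ribosomal proteins over 6 (0.0147), and the lysosome and proteasome lists over 16 and 21 (both 0.05 when rounded). That cut dropped ALDH3A1, the 1 AhR member higher with glycyrrhizin. Of 26 proteasome subunits 16 were lower and 5 passed when adjusted over the list alone, among them PSMB5 (−1.37) and PSMD14 (−1.17), and the list's adjusted p was 0.0599. Of the immediate early genes, FOS (−2), DUSP1 (−1.26) and KLF4 (−1.16) passed over their list alone, as did PFKL (0.97) over the glucose list, CCNA2 (0.78) over the mitosis list and the proton pump subunit ATP6V0D1 (−0.8) over the lysosome list. Of these members CYP1B1 alone passed over all genes, and the others were chosen after their values were seen. Of 9 fibroblast and stellate cell markers 7 were higher (list adjusted p = 0.315). At an unadjusted p under 0.05 there were 1292 genes against a mean of 694.1 by chance, a number whose spread was not estimated. The variance trend called 202 genes, 49 higher and 153 lower, and included all 7. Limma gave 5 genes without ursodeoxycholic acid replicate 1, 4 without control replicate 2 or ursodeoxycholic acid replicate 2, 3 without control replicate 1, control replicate 3 or ursodeoxycholic acid replicate 3, 1 without silymarin replicate 3, 0 without any other array and 0 in a fit on these 6 arrays alone. The AhR list's adjusted p ran from 0.0238 to 0.184 without single arrays and missed the threshold without control replicate 3 (0.0537), glycyrrhizin replicate 3 (0.184) and silymarin replicates 1, 2 and 3 (0.0621, 0.0994 and 0.0836).

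**Figure D3:**
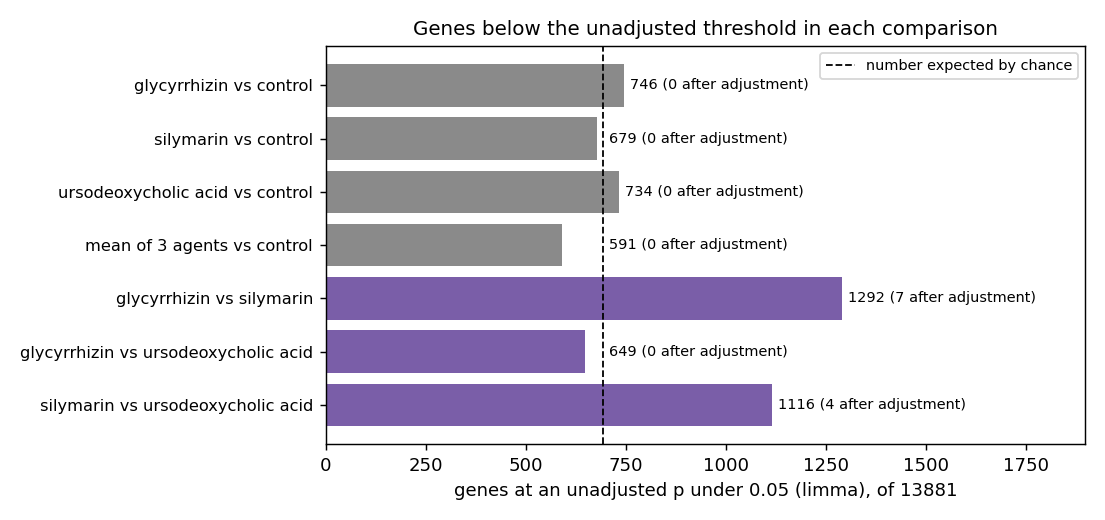
Number of the 13881 genes at an unadjusted p under 0.05 in limma (bars) in each of the 7 comparisons, with the number past the adjusted threshold in parentheses and the mean of 694.1 expected by chance as a dashed line. The spread of the chance number was not estimated. The comparisons of silymarin with glycyrrhizin (1292) and with ursodeoxycholic acid (1116) exceed the others, which lie between 591 and 746.

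Silymarin against ursodeoxycholic acid. Of the 4 genes past the threshold in limma, 3 had also passed between glycyrrhizin and silymarin. Both comparisons use the same silymarin arrays, so the second result does not replicate the first. DCPS was 7.83-fold lower with silymarin (log2 difference −2.97, SE 0.33, adjusted p = 0.0381), while CLCN2 was 2.56-fold and MIEN1 2.54-fold higher (both adjusted p = 0.0475). The transporter gene SLC22A11 was higher by 2.92 (SE 0.37, adjusted p = 0.0475), with a mean log2 intensity of 4.04 and ursodeoxycholic acid arrays at 1.46 to 2.42, near the lowest deposited value. CYP1B1 (1.1), CYP1A2 (1.1) and, in the other direction, ALDH3A1 (−0.83) passed when adjusted over the AhR list alone. So did FOS (1.78), FOSB (1.48), KLF4 (1.03) and EGR3 (0.72) over the immediate early list and the conjugating enzymes UGT2B4 (1.05) and SULT1A1 (1.37) over the drug metabolism list. None of these 9 passed over all genes, and all 9 were chosen after their values were seen. The AhR list's adjusted p was 0.0634 (fry 0.00929). In this comparison fry called 3 of the 34 lists, and camera with an estimated correlation called 0. Of 9 fibroblast and stellate cell markers 7 were lower with silymarin (list adjusted p = 0.0918).

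Cytosolic ribosomal proteins were higher with silymarin as a list, with 10 of 11 measured members higher and a median of 0.45 (camera adjusted p = 0.0104; fry 0.0596), 11 of the 48 listed. With an estimated correlation the adjusted p = 0.261, and no member passed by itself, RPS16 differing by 0.76 (SE 0.43) and RPL37, chosen with it after their values were seen, by 0.62 (SE 0.32), or −0.04 when its probes were averaged. RPS16 differed by 0.41, 1.36 and 0.5 without ursodeoxycholic acid replicates 1, 2 and 3, and RPL37 by 0.36 without silymarin replicate 3. Without ursodeoxycholic acid replicate 3 the list's adjusted p was 0.263, without silymarin replicate 1 it was 0.0557 and without silymarin replicate 3 it was 0.0682, in a range from 0.00033 to 0.263 without single arrays. When the dimmer 50% of probes were left out, camera called this list over 6 genes (adjusted p = 0.0107) and the AhR list over 3 (0.000325), both higher with silymarin. The AhR call came without ALDH3A1, which was dropped as dim and differed by −0.83. At an unadjusted p under 0.05 there were 1116 genes, and the variance trend called 16, of which 11 were higher with silymarin, MIEN1 and CLCN2 among them, and 5 lower, DCPS among them, while SLC22A11 was not called. Leaving out single arrays gave 28 genes without ursodeoxycholic acid replicate 3 and 2 without control replicate 1 or 3, and 0 without any other array, in a fit on these 6 arrays alone or with all probes as features.

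Glycyrrhizin against ursodeoxycholic acid. No gene passed between these agents in limma, and the lowest adjusted p was 0.388. MIEN1 differed by −0.25 (95% interval −0.65 to 0.14), CLCN2 by −0.05 (−0.45 to 0.34), CYP1A2 by −0.19 (−0.65 to 0.27) and CYP1B1 by −0.55 (−0.97 to −0.14, adjusted p = 0.882). When adjusted over the list alone, BAAT was higher with glycyrrhizin (1.13, adjusted p = 0.049), AFP lower (−0.99, adjusted p = 0.0165) and RPS16 higher (1.57, adjusted p = 0.0443), while over all genes each had an adjusted p of 0.882. With no correction for the 34 lists, 3 such members could arise by chance. The genes of this comparison were chosen after their values were seen. Of 15 drug metabolism enzymes 12 were higher with glycyrrhizin, UGT2B4 by 0.76, and the list's adjusted p was 0.365, or 0.0482 over 9 genes, past the threshold, when the dimmer 50% of probes were left out. The variance trend also called 0 genes, with 649 at an unadjusted p under 0.05, and camera, the estimated correlation and fry called 0 lists, with 3 at an unadjusted camera p under 0.05.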

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

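The test of probes without a gene symbol was chosen after the data were seen. These probes entered no comparison of genes, and some of them passed the same limma test by themselves. Of 11911 such probes, 3 differed between glycyrrhizin and silymarin in limma, all lower with glycyrrhizin, and 2 of the same probes differed between silymarin and ursodeoxycholic acid, both higher with silymarin. Probe PH_hs_0039308 differed by −1.59 (SE 0.18, adjusted p = 0.033) and by 1.47 (adjusted p = 0.0339). Probe PH_hs_0002361 differed by −1.57 (SE 0.2, adjusted p = 0.0499) and by 1.67 (adjusted p = 0.0339). Both are bright, with mean log2 intensities of 12.93 and 13.01, and follow the direction of MIEN1 and CLCN2. No explanation was tested for them.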

How the results depend on the processing

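Offsets and the lists without single arrays were chosen after seeing the data; the other alternatives were planned. The counts for the mean of the agents and for all 3 agents in the same direction were 0 in each setting except where given, and the count between glycyrrhizin and ursodeoxycholic acid was 0 in each. For glycyrrhizin, silymarin and ursodeoxycholic acid against control in turn, the counts were 17, 4 and 6 with the variance trend (3 for the mean of the agents), 3, 1 and 0 with array weights, 2, 1 and 0 without the dimmest 25% of probes, 3, 2 and 2 without the dimmer 50%, 2, 1 and 0 with an offset of 16 and 7, 2 and 6 with an offset of 50 (3 for the mean). For glycyrrhizin alone, centring arrays on the median or averaging the probes of a gene gave 1. The 7 genes that differ between glycyrrhizin and silymarin became 202, 20, 18, 68, 18 and 139 in the same order, and between silymarin and ursodeoxycholic acid the 4 became 16 with the variance trend, 10 with an offset of 50, 7 with averaged probes and 0 with all probes as features. Both fell to 0 on the compared groups alone, which leaves fewer arrays to estimate the spread. Otherwise the cause was not tested.

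Without single arrays, counts ran from 0 to 0 for glycyrrhizin, silymarin, the mean of the agents, all 3 together and glycyrrhizin against ursodeoxycholic acid, from 0 to 2 for ursodeoxycholic acid, from 0 to 5 for glycyrrhizin against silymarin, from 0 to 28 for silymarin against ursodeoxycholic acid, from 0 to 1 for lists by agent and from 0 to 3 for lists between agents. Lists by agent went from 0 to 3 without the dimmer 50%. Lists between agents went from 2 to 7 there, to 5 with an offset of 50, 4 with fry and 0 with an estimated correlation. Quantile normalization tested little, since the values were already so normalized. Replicate numbers were not taken to pair the arrays: deviations of same-numbered arrays correlated at −0.38 to 0.36, with 9 of 18 pairs over 0.1, and 5 of 12 arrays lay closest to their own number. With the replicate block the counts between glycyrrhizin and silymarin and between silymarin and ursodeoxycholic acid became 0 and lists between agents 1. Of 3293 values of single genes under other settings, 3059 kept direction and side of the threshold, 133 lost and 96 gained the threshold and 5 turned: RPL37 to 0.09 with ursodeoxycholic acid and −0.04 between silymarin and it when probes were averaged, and CLCN2, between glycyrrhizin and ursodeoxycholic acid, to 0.02 with array weights, 0.02 without glycyrrhizin replicate 3 and 0 without ursodeoxycholic acid replicate 1, within −0.16 to 0.02 without single arrays. No background values were used, so a limit set by signal over background was not analysed here.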

Other observations

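The tests of the probe table, of the hepatocyte programme, of poorly hybridizing probes, of a batch, of silymarin in genes chosen without it and of second probes of the 4 genes were chosen after the result was seen, as was the grouping of glycyrrhizin with ursodeoxycholic acid. The lists of other cell types were written after the low liver levels were seen and before their own levels were. How many of their genes hepatocytes also express is not given in the sources used here.

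Glycyrrhizin and ursodeoxycholic acid arrays, set as 1 group against control and silymarin arrays, differed in 4 genes in limma, all lower: MIEN1 (log2 difference −1.44, SE 0.13, adjusted p = 0.00333), CLCN2 (−1.35, SE 0.13, adjusted p = 0.00348), CYP1A2 (−1.22, SE 0.15, adjusted p = 0.0263) and HIPK3 (−1.45, SE 0.18, adjusted p = 0.0263). The variance trend called 128 genes. The other ways of pairing the groups, glycyrrhizin with silymarin and silymarin with ursodeoxycholic acid, gave 0 genes each in limma, with 591 and 763 at an unadjusted p under 0.05 against 1209 for the first, and 0 and 2 with the variance trend.

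Chance in the 3 control arrays was tested on genes chosen without the silymarin arrays, since it would leave silymarin beside the other agents. The variance trend called 9 genes between both agents and control without those arrays (limma 0, with 755 at an unadjusted p under 0.05). In 7 of the 9 silymarin lay from the mean of the other 3 groups toward control after Holm adjustment over the 9. Among them were MIEN1 (log2 difference 1, adjusted p = 0.000293), CLCN2 (0.95, 0.000437), HIPK3 (1.23, 0.000812) and CYP1A2 (0.79, 0.00499). OAF (0.53), GINS4 (1.04) and RAB5B (0.55) each had an adjusted p of 0.0375, while SYNE2 (0.23, 0.295) and CKS1B (0.39, 0.0816) did not pass. The spread came partly from the arrays that chose the genes, so these p-values may be too small. At 0.00499 or lower they argue against chance in the control arrays for MIEN1, CLCN2, HIPK3 and CYP1A2. For OAF, GINS4 and RAB5B, which passed at 0.0375, p-values that are too small could account for the pass. Chance therefore stays open for these 3 genes, as it does for SYNE2 and CKS1B. For genes at large such chance also stays open, since glycyrrhizin minus silymarin and ursodeoxycholic acid minus control, which share no array, correlated across genes at 0.08, under the 95th percentile of 0.13 of 99 regroupings. Faults of single probes stay open. Of the 128 genes 15 had a second probe, and 12 of these had it in the direction of the first, a share of 0.8 (exact binomial 95% interval 0.52 to 0.96). That interval treats genes on the same arrays as independent, and the share among genes not called was not measured. Of the 4 genes, 1, HIPK3, has a second probe, dim at 5.59 and different by −0.3 (SE 0.24). The only probe of CYP1A2 averaged 10.68, above the medians of the lists of liver products, and what it reads was not tested. A hybridization batch that follows the groups cannot be told apart from the agents for these 4 genes, because no label gives a batch, so a shared effect of both agents is a hypothesis and no more.

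Liver product genes near the median of all genes were unexpected for cells labelled HepG2. A probe table out of register with the values is argued against, since the proteasome list's median exceeded that of 100% of 10000 random lists of its size. RNA from cells that do not express the hepatocyte programme stays open, since the median percentile of the 4 liver lists among random lists, 37.35 (52.8, 35.8, 30.9 and 38.9), only restates the pattern, and so do probes of liver genes that hybridize poorly, as 11.4% of 79 such genes lay above the 75th percentile of all genes and no array of known liver RNA was at hand. A list of neuroblast and sympathetic neuron genes, 18 measured and 0 of them in the 34 lists, lay at the 99.6th percentile (median 8.41; TH 12.49, STMN2 11.08, ISL1 10.15), while glial, simple epithelium, melanocyte, osteoblast and lung epithelium lists lay at 2.1, 9.5, 67.9, 68.7 and 59.4. That is consistent with neuroblast-like cells as a hypothesis, though GAP43 (5.2), CHGB (5.66) and ELAVL4 (3.28) were dim and ANXA1 (15.82), IGFBP7 (15.82), S100A6 (15.56), VIM (15.53) and CDH2 (14.82), in none of these lists, were far brighter, so other cell types stay open (9 fibroblast and stellate cell markers lay at the 25.9th percentile). Every group carries the same cell label, so no biological difference between groups was tested for this pattern.

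Other splits of the same arrays were counted for each result. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 7 genes between glycyrrhizin and silymarin and the highest other gave 0, with 1 of 10 as large, and between silymarin and ursodeoxycholic acid the real split gave 4 and the highest other 1, with 1 of 10 as large. With the variance trend the first comparison gave 202 genes in the real split and at most 1 in another. The second gave 16 genes in the real split and 25 with silymarin replicates 1 and 2 and ursodeoxycholic acid replicate 1 set against the rest, so that 2 of 10 were as large. Against control the variance trend gave 17, 4 and 6 genes for glycyrrhizin, silymarin and ursodeoxycholic acid, and 0 in any other split. In limma the real count was 0 for glycyrrhizin, silymarin and ursodeoxycholic acid against control and for glycyrrhizin against ursodeoxycholic acid, so 10 of 10 splits were as large, and the highest others were 0, 1, 0 and 0. For the mean of the agents and for genes changed by all 3 agents the real count was also 0, which each of the 100 splits and 100 regroupings meets by construction, so these counts say nothing about chance. The highest others gave 20 genes and 1. The 20 arose with control, glycyrrhizin and silymarin replicates 2, which share a replicate number, set against the rest. With the variance trend that split gave 91 genes against 3 in the real split, for which 4 of 100 splits were as large. Splits with several times the real count may point to a structure of the arrays that the groups do not describe, though how high the highest of 100 splits runs without one was not analysed here.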
